A study of Sus scrofa with 6 samples.

How the data were processed

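RNA was measured in cervical spinal cord of 6 male pigs aged 140 days, 3 wild type and 3 carrying a deletion of UBE3A on the maternal allele, with 1 library per animal. The tissue is that of the source name; the sample titles put the word brain before it, and the level of the cord is not stated. Per the labels' protocols, tissue was flash frozen, RNA was purified on columns, and poly(A)-selected, strand-preserving libraries were sequenced as paired ends on an Illumina NovaSeq. The aligner, the counting program, the annotation release and the genome build are not given in the sources used here, so no coordinates are printed. Whether the counting used strand is not stated either, so reads of a gene and of an antisense partner cannot be told apart, including reads antisense to UBE3A.

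The authors deposited, per the file headers, a whole-number count of exon reads for each of 28965 Ensembl genes in every library, with a blank where a gene had no reads. They also deposited RPKM and TPM columns, which were checked for their unit and not used in any test. A further deposited signal column is headed CPM; count divided by this value was a constant within each library, and its column sums ranged from 917605 to 1075790, so the authors scaled it by a factor per library. The authors' deposited table for the series gives a signed fold change as a score, with a p-value and a false discovery rate, for 26846 protein-coding and lncRNA genes. How those p-values were computed is not given in the sources used here. Of the genes, 16246 were named in the files, and 777 further IDs took a symbol from a name table.

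All values computed here start from the exon read counts. Totals ranged from 17181003 to 22492366 reads, and 3 reads, the smallest count taken as a floor, correspond to between 0.133 and 0.175 CPM. The floors cover counting error only, because the reads carry no molecular identifiers, while the intervals of log2 fold changes also hold the variation between animals. Genes were kept by filterByExpr with the genotype groups, which left 14566, scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust settings and Benjamini-Hochberg adjustment. An adjusted p under 0.05 counts as past the threshold. Levels are TMM-scaled CPM, the count of a gene over the scaled total of its library, given as mean ± SD with n = 3 per group. Log2 fold changes are deletion over wild type, and their standard errors were derived from the quasi-likelihood statistic.

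Lists of genes for cell types, tissues and pathways, 33 in all, were fixed before the data were examined, and each had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 33 lists. Camera with an estimated correlation and fry were run beside it. The genes named in the text follow a rule fixed at the same time. It takes UBE3A and the measured genes of its region, the 12 largest rises and the 12 largest falls among genes past the threshold with a symbol, a mean log2 CPM of at least 1 and no overlap between the groups, and up to 4 members of each list by p. Some genes that the rule takes are left out of the text. Genes outside this rule are said to have been chosen after their values were seen. Principal components used log2 CPM with a prior count of 2.

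The test was run on simulated data for the comparison of maternal deletion with wild type, drawn for the real genes from the real means, library sizes and dispersions, with 200 changed genes. Over the 14422 genes its filter kept, edgeR recovered 47 of 100 genes changed 2-fold and 87 of 100 genes changed 4-fold, with 10 false calls among 144. DESeq2 1.42.0, over 14562 genes, recovered 67 and 89 of the same 2 sets with 51 false calls among 207. Limma voom with quality weights recovered 43 and 86, with 10 false calls among 139. A list shifted 1.5-fold was called by camera with either correlation and by fry, and none of 4 unshifted lists was. Genes were drawn independently of each other, so the simulated lists held no inter-gene correlation. The simulation therefore does not show how the list tests behave where the genes of a list vary together.

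Libraries were compared pairwise before averaging, and none of the 15 pairs came within sampling noise, with a chi-square per degree of freedom of at least 29.5. The animal IDs begin with 14 in 1 animal of each genotype and with 15 in the other 2. What this prefix stands for is not stated, and it was treated as a possible batch. The alternatives were other scalings, other filters, DESeq2, voom with quality weights, the ID prefix as a block, a neuron minus oligodendrocyte covariate and leaving out each library in turn. A covariate for nerve root and meninges genes, bias-adjusted deviances and a likelihood ratio test were added after the data were seen. Neighbours of UBE3A were taken from a RefSeq table of assembly Sscrofa11.1, used for names and order only.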

Results

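Cervical spinal cord was profiled by poly(A) RNA sequencing in 6 male pigs of 140 days. The 3 wild-type animals were set against 3 animals that inherited a deletion of UBE3A from the mother. UBE3A encodes an E3 ubiquitin ligase that neurons express from the maternal allele, and its loss underlies Angelman syndrome in people, so the comparison asks how the cord transcriptome differs when the maternal copy is missing. Libraries held 17181003, 21298505 and 21266965 exon reads in wild-type replicates 1 to 3, and 21352677, 20294026 and 22492366 in deletion replicates 1 to 3. The labels name separate animals, and replicate numbers only name them.

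UBE3A RNA (ENSSSCG00000004832) fell in the deletion animals to 38.2% of the wild-type level, with a 95% interval of 30.8 to 47.3%. It stood at 57.0, 65.5 and 60.6 CPM in wild-type replicates 1 to 3 and at 21.4, 27.1 and 21.4 CPM in deletion replicates 1 to 3. Group means were 61.0 ± 4.25 CPM and 23.3 ± 3.26 CPM (SD, n = 3 each), a log2 fold change of -1.39 (SE 0.13; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p 0.0253). The groups did not overlap, and an exact two-sided permutation test of the 6 levels gave p = 0.1, the smallest that 3 against 3 allows. All 6 libraries therefore carried the UBE3A level of their label. In the animals whose ID begins with 14, 1 per genotype, the deletion level was 0.376 times the wild-type level; with the prefix as a block the log2 fold change was -1.39 (edgeR quasi-likelihood adjusted p 0.0526). The call of UBE3A in maternal deletion was also lost without wild-type replicate 1 (edgeR quasi-likelihood adjusted p 0.152), deletion replicate 1 (0.0728), deletion replicate 2 (0.0886) or deletion replicate 3 (0.0822), and kept without wild-type replicate 2 (0.0482) or 3 (0.00514).

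**Figure D1:**
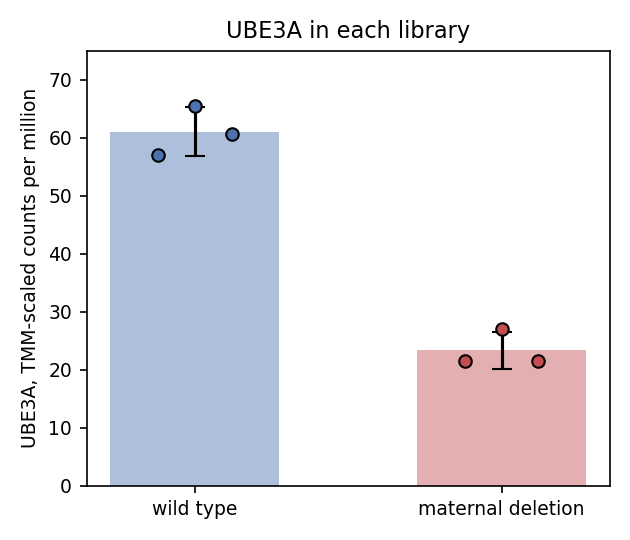
UBE3A in TMM-scaled CPM on a linear axis from 0. Points are single libraries, bars are the means of 3 libraries and error bars are 1 SD; the deletion libraries lie between 21.4 and 27.1, below the wild-type range of 57.0 to 65.5.

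Around UBE3A, no other gene of the region list passed the threshold. GABRA5, which encodes a GABA-A receptor subunit, stood at 3.84 ± 0.785 CPM in wild type and at 8.38 ± 2.34 CPM in the deletion group. Its log2 fold change was 1.12 (SE 0.27), with an edgeR quasi-likelihood adjusted p of 0.0887. The authors' deposited table lists it at 2.20-fold with a false discovery rate of 0.0169. The paternally expressed genes NDN, MAGEL2 and MKRN3 gave log2 fold changes of 0.15 (SE 0.14), 0.18 (SE 0.34) and 0.36 (SE 0.36). TUBGCP5, NIPA2, NIPA1 and HERC2 gave 0.36 (SE 0.16), 0.15 (SE 0.11), 0.40 (SE 0.27) and 0.04 (SE 0.14), and HERC2 changed sign under total-count and upper-quartile scaling. GABRG3 had 10 reads over all libraries and was not tested. Adjusted over the list alone, UBE3A was lower and GABRA5 was higher. SNRPN, SNURF, ATP10A, OCA2 and CYFIP1 matched no row by symbol and were not analysed here.

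Across the transcriptome, genes of connective tissue, smooth muscle and peripheral myelin made up the largest falls in the deletion group. ACTA2 and MYH11, the actin and myosin heavy chain of smooth muscle, fell by 5.83 (SE 0.95) and 5.06 (SE 0.84) on the log2 scale, from 414 ± 379 and 343 ± 270 CPM to 7.23 ± 3.64 and 10.3 ± 6.47 CPM. PRX, the periaxin of peripheral myelin, fell by 5.46 (SE 0.91), and ELN, which encodes elastin, fell by 4.18 (SE 0.48). The rises were smaller, and their largest members included SLC7A14 with 3.18 (SE 0.41) and FIBCD1 with 3.10 (SE 0.53). Of 14566 genes tested, 149 passed the threshold, 26 higher and 123 lower.

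Among the other large falls were ADAMTS8 with -5.71, COL6A6 with -4.99, CLDN1 with -4.88, PI16 with -4.81, MYL9 with -4.41, GAS2L3 with -4.25 and MRGPRF with -4.22. COL6A6 is a collagen VI chain, CLDN1 a tight junction protein and MYL9 a myosin light chain. The rises included the potassium channel subunit genes KCNH6 with 2.35 and KCNS2 with 2.16, and TRPM8, the cold-sensing channel, with 1.57. They also included CRYZL1 with 2.25, NYAP2 with 1.78, KLHL40 with 1.64, TMEM132E with 1.40, LINGO3 with 1.39, SYNDIG1L with 1.38 and ARPP21 with 1.32. NYAP2 stood at 1.69 ± 0.123 CPM in wild type and 5.81 ± 1.91 CPM in the deletion group, and KLHL40 at 3.57 ± 0.765 and 11.1 ± 1.16 CPM. The edgeR quasi-likelihood adjusted p of the genes named in this paragraph ranged from 0.0407 to 0.0497, and 63 of the 149 calls lay between 0.049 and 0.05. Over all tested genes, the groups did not overlap in 26.4%. Chance gives 10% for any single gene. Genes vary together, so the share in a single split can lie far from 10% by chance, and the contrast is not a test.

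The count of calls rested on single libraries and on the test. By edgeR's quasi-likelihood test it was 0 without wild-type replicate 1, without deletion replicate 2 and without deletion replicate 3, where 2420, 1888 and 2380 genes had an unadjusted p under 0.05, against 2942 with all libraries. It was 6 without deletion replicate 1, 9 without wild-type replicate 2 and 759 without wild-type replicate 3. With the ID prefix as a block it was 3, namely DCN, COL1A2 and PTGIS, the last chosen after its values were seen; in the animals of prefix 15 alone, 2 against 2, it was 0 with 1608 genes at an unadjusted p under 0.05. DESeq2 gave 1362 genes, including all 149: genes changed in maternal deletion, higher, numbered 569, and genes changed in maternal deletion, lower, numbered 793. Under total-count scaling the split was 6 higher and 94 lower, and under RLE scaling 9 higher and 93 lower.

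Of the lists fixed beforehand, the meninges and fibroblast matrix list held the most falls. DCN, which encodes the proteoglycan decorin, fell by 2.70 (SE 0.21) on the log2 scale, from 165 ± 29.8 to 25.4 ± 5.73 CPM; its edgeR quasi-likelihood adjusted p, 0.0127, was the smallest of all genes together with that of PTGIS. The fibrillar collagen genes COL1A2, COL3A1 and COL1A1 fell by 2.35 (SE 0.22), 3.24 (SE 0.31) and 2.83 (SE 0.38). Of 16 tested members 10 fell and none rose, with 13 lower adjusted over the list alone, and the median log2 fold change was -2.09. The list passed the camera test (adjusted p 1.45e-40; adjusted p = 0.1003 with an estimated correlation). The immediate early genes, which respond within minutes to stimulation of a cell, fell in 5 of 20 members, namely FOS by 2.78 (SE 0.28), FOSB by 3.34 (SE 0.36), IER3 by 3.12 (SE 0.40), EGR1 by 2.48 (SE 0.33) and ZFP36, chosen after its values were seen, by 1.25. FOS stood at 111 ± 14.2 CPM in wild type and 16.1 ± 5.91 CPM in the deletion group. Adjusted over the list alone 16 were lower, the median was -1.41, and the camera adjusted p was 1.86e-28 (adjusted p = 0.196 with an estimated correlation).

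**Figure D2:**
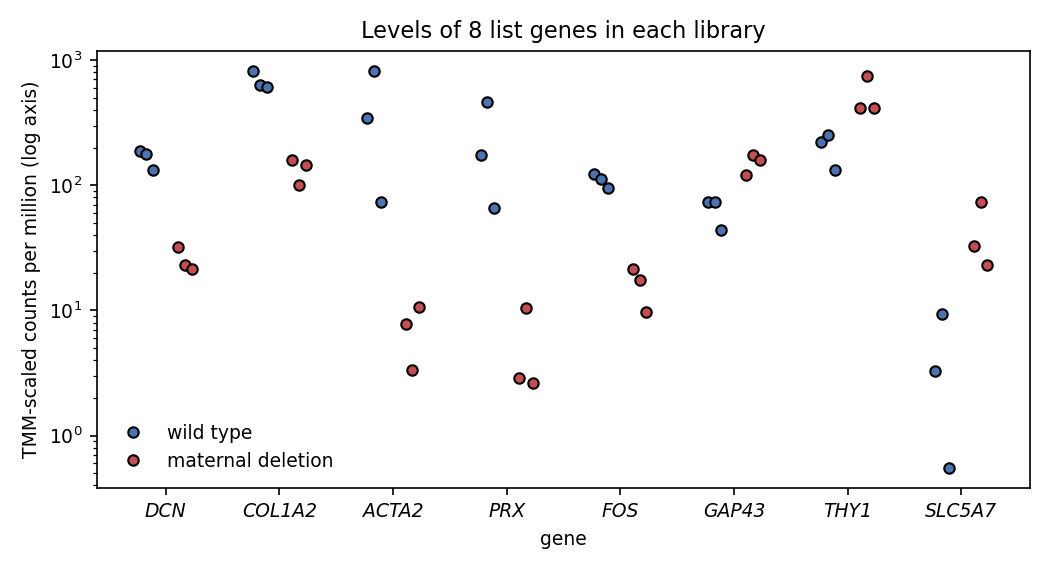
Levels of 8 list genes in each library, in TMM-scaled CPM on a log axis; each point is 1 library, blue for wild type and red for maternal deletion. DCN lies between 132 and 187 in wild type and at 21.3 to 32.0 in the deletion libraries, while ACTA2 spreads from 73.8 to 823 within wild type.

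Vessel and peripheral nerve genes were lower too. In the endothelium and mural list, ACTA2, MYH11 and TAGLN, a smooth muscle actin-binding protein that fell by 3.49 (SE 0.60), passed among 16 members, and VWF of endothelium gave -0.98 (SE 0.18) at an edgeR quasi-likelihood adjusted p of 0.0552. The list median was -0.91, 11 members were lower adjusted over the list alone, and the camera adjusted p was 2.12e-13 (adjusted p = 0.285 with an estimated correlation). In the Schwann cell and nerve root list PRX alone passed among 10 members, while EGR2 and DRP2 gave -3.12 and -1.19 and L1CAM, an adhesion molecule that neurons also make, gave 1.36. Its median was -1.003, with 7 lower and 1 higher adjusted over the list alone, at a camera adjusted p of 1.71e-06 (adjusted p = 0.285 with an estimated correlation).

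Several immune and stress lists were lower with 1 member or none past the threshold in each. In the reactive glia and acute phase list SOCS3 fell by 2.41 (SE 0.29), while CCL2, TIMP1 and VIM gave -3.10, -1.42 and -2.69; the median was -0.88 and 6 were lower adjusted over the list alone (camera adjusted p 3.07e-08; adjusted p = 0.1003 with an estimated correlation). In the glucocorticoid response list CEBPD fell by 1.79 (SE 0.22) and FKBP5 gave -0.58; the median was -0.38 and 7 were lower adjusted over the list alone (camera adjusted p 2.34e-05; adjusted p = 0.288 with an estimated correlation). In the microglia and macrophage list LYVE1 fell by 2.97 (SE 0.44), and CD163 and MRC1 gave -2.69 and -1.90; these 3 genes, the members lower adjusted over the list alone, are known from macrophages of vessels and meninges, and the median was -0.12 (camera adjusted p 0.00264; adjusted p = 0.325 with an estimated correlation). Leaving out deletion replicate 1, 2 or 3 or wild-type replicate 3 moved this median to -0.0736, -0.19, -0.22 and -0.19. The MHC class II list had a median of -0.68, with SLA-DQB1 and CD74 at -1.22 and -0.68, none past the threshold over all genes and 5 lower adjusted over the list alone (camera adjusted p 2.60e-05; adjusted p = 0.288 with an estimated correlation). The blood list had a median of -0.98 with S100A12 at -2.82 and no member past either threshold (camera adjusted p 0.00630; adjusted p = 0.285 with an estimated correlation). Its median was -0.18 without wild-type replicate 1, -0.65 without deletion replicate 1 and -0.60 without deletion replicate 3, and the call was lost in prefix 15 alone (median -0.35, camera adjusted p 0.0696). All 53 tested ribosomal protein genes had negative values, RPS16 and RPL10 at -0.41 and -0.40, with a median of -0.30 and none past either threshold (camera adjusted p 5.93e-10; adjusted p = 0.552 with an estimated correlation). Ribosomal protein genes have many near-identical pseudogene copies, so their counts are uncertain; the median was -0.21 without wild-type replicate 1 and -0.48 without wild-type replicate 3.

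Neuronal lists were higher, with few single genes past the threshold. All 21 general neuron genes had positive values and their median was 0.98, with GAP43 and THY1 at 1.25 (SE 0.23) and 1.37 (SE 0.32); none passed over all genes and 16 were higher adjusted over the list alone (camera adjusted p 2.66e-13; adjusted p = 0.280 with an estimated correlation). All 13 motor neuron genes were positive too, with a median of 2.38. SLC5A7, the choline transporter, stood at 4.38 ± 4.47 CPM in wild type and 42.9 ± 26.3 CPM in the deletion group, and CHAT, which makes acetylcholine, at 0.767 ± 0.916 and 7.27 ± 5.17 CPM. ACHE and MNX1 gave log2 fold changes of 1.46 (SE 0.36) and 3.05 (SE 0.79). None of the 13 passed over all genes and 11 were higher adjusted over the list alone (camera adjusted p 5.86e-08; adjusted p = 0.288 with an estimated correlation).

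Among transmission genes, GRIA4, an AMPA receptor subunit, rose by 0.67 (SE 0.10), from 31.5 ± 1.47 to 50.0 ± 2.43 CPM, and GRIN2D and GRIN2A gave 1.22 and 2.54. The glutamate list had a median of 0.48 over 22 genes, 4 of them higher adjusted over the list alone (camera adjusted p 3.15e-05; adjusted p = 0.285 with an estimated correlation). The GABA and glycine list had a median of 0.55 over 21 genes with GABRG1, GLRA1 and GLRB at 0.62, 1.79 and 0.55, none past over all genes and 7 higher adjusted over the list alone (camera adjusted p 1.60e-05; adjusted p = 0.367 with an estimated correlation). Without deletion replicate 3 the medians of the glutamate and the GABA and glycine lists were 0.27 and 0.24 (camera adjusted p 0.00552 and 0.0180). The voltage-gated channel list had a median of 0.46 over 28 genes with SCN8A at 1.86, none past over all genes and 4 higher adjusted over the list alone (camera adjusted p 1.60e-05; adjusted p = 0.285 with an estimated correlation). Of 8 tested dorsal root ganglion genes TRPM8 rose, RET and SCN9A gave 2.15 and 2.87, and 3 were higher adjusted over the list alone; the median was 0.82 (camera adjusted p 0.00823; adjusted p = 0.280 with an estimated correlation). This call was lost with no filter (median 0.05, camera adjusted p 0.0689), with voom (0.0765) and with the neuron minus oligodendrocyte covariate (0.0557), and under DESeq2 the median was -0.00126. All 30 proteasome genes had positive values, PSMD2 and PSMD12 at 0.52 and 0.53, with a median of 0.22 and none past either threshold (camera adjusted p 7.67e-05; adjusted p = 0.373 with an estimated correlation). Nuclear oxidative phosphorylation genes were positive in 47 of 49 cases, NDUFA9 and ATP5F1A at 0.54 and 0.45, with a median of 0.18 and none past either threshold (camera adjusted p 1.27e-04; adjusted p = 0.671 with an estimated correlation). Without wild-type replicate 3 this median was 0.03 and the call was lost (camera adjusted p 0.165), as it was with the neuron minus oligodendrocyte covariate (0.11, 0.116), while without wild-type replicate 1 the median was 0.30 (3.30e-08).

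**Figure D3:**
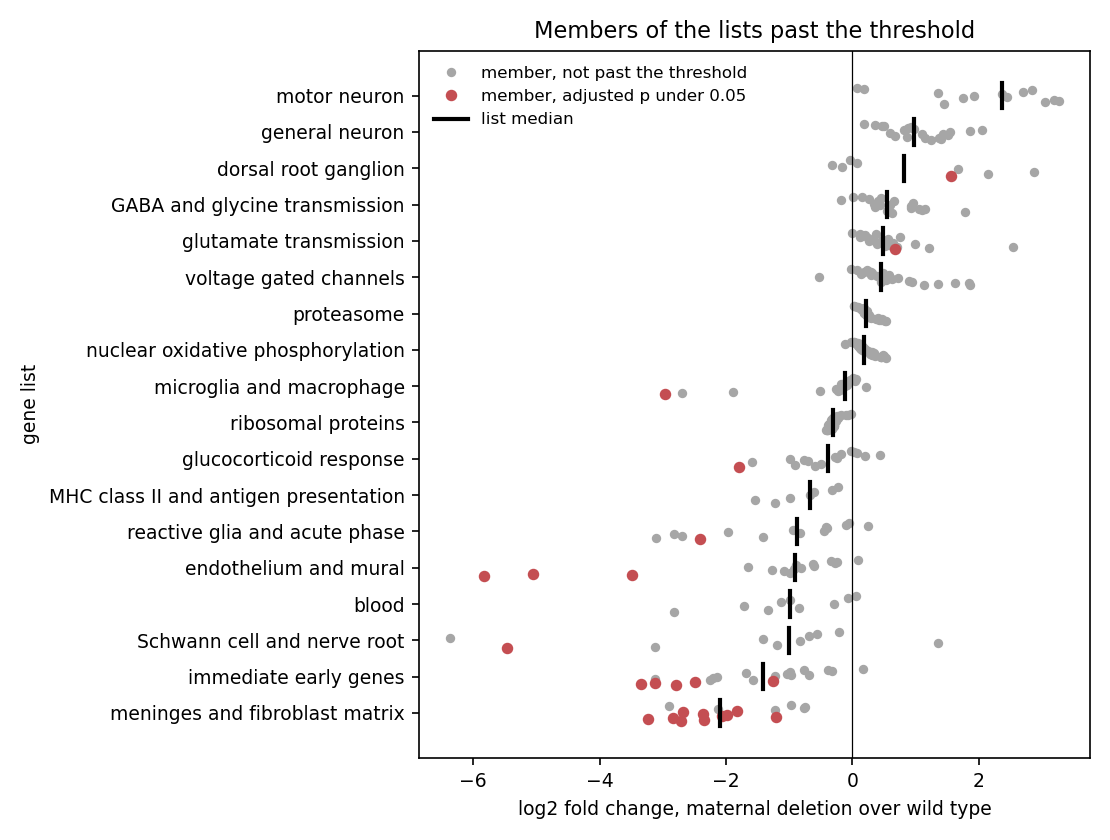
Log2 fold change, deletion over wild type, of every tested member of the 18 lists past the camera threshold. Each point is a gene, red where it passed the threshold over all genes and grey where it did not, and black bars are list medians, which run from -2.09 for the matrix list to 2.38 for the motor neuron list.

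In all, 18 of the 33 lists passed by camera at the preset correlation, 8 higher and 10 lower, 0 passed with an estimated correlation, and 4 passed by fry, which asks whether a list's genes move on balance in a shared direction. Those 4 were the matrix, immediate early, reactive glia and dorsal root ganglion lists. In the 9 other splits of the 6 libraries into 3 and 3, between 12 and 20 lists passed at the preset correlation. The general neuron list and other signs of library make-up also set wild-type replicate 3 apart. Wild-type replicate 3 had the lowest general neuron mean, 6.40 log2 CPM against 6.99 and 7.29 in the other wild-type libraries, and its mitochondrial share of reads was 5.98% where the other 5 libraries had 9.13 to 12.6%. The HOXC8 level, chosen after its values were seen, was 1.97 CPM in that library and 23.2 to 32.1 CPM in the other 5.

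Glial and other lists stayed within the threshold in the fit of all libraries without a block. Mature oligodendrocyte genes had a median log2 fold change of 0.19 over 20 genes, with OLIG1 and MOG at 0.43 and 0.33 (camera adjusted p 0.159). Oligodendrocyte precursor genes had a median of 0.17 with MATN4 at -0.81 (camera adjusted p 0.981), and astrocyte genes 0.36 with FGFR3 at 0.62 and ALDH1L1 at -0.79 (camera adjusted p 0.0705). Reported UBE3A targets had a median of -0.04 over 23 genes (camera adjusted p 0.383); ALDH1A2 and ALDH1A3, enzymes of retinoic acid synthesis, gave -1.62 (SE 0.32) and -3.07 (SE 0.63) and were the 2 members lower adjusted over the list alone. Other imprinted genes had a median of 0.13 with MEST at 0.95 and KCNQ1 at -2.01 (camera adjusted p 0.546), and the UBE3A region 0.27 (camera adjusted p 0.544). Medians were -0.04 for heat shock genes (camera adjusted p 0.629), -0.15 for interferon genes (0.138), -0.05 for clock genes (0.0854), 0.21 for cholesterol synthesis (0.157) and -0.35 for skeletal muscle (0.546). The 13 mitochondrially encoded mRNAs had a median of 0.04, which turned negative under each other scaling (camera adjusted p 0.546). HOX paralogs 4 to 8 had a median of -0.21 (camera adjusted p 0.447), HOX paralogs 9 to 13 a median of 0.39 (0.200), and ependyma and cilia genes -0.47 (0.166). Apart from the region and target lists, HOXC10 in HOX paralogs 9 to 13 was the only member of these 15 lists past the threshold adjusted over the list alone. With all libraries, the astrocyte list passed with the ID prefix as a block (camera adjusted p 0.0364), with no filter (0.0203), with DESeq2 (0.0286) and with voom (0.0471), and voom also called the oligodendrocyte (0.0402), ependyma (0.0130) and cholesterol (0.00472) lists. DESeq2 also called the clock list (0.0468). The neuron minus oligodendrocyte covariate, which holds the oligodendrocyte list itself, called the oligodendrocyte (median 0.72, camera adjusted p 1.76e-11), cholesterol (0.52, 5.79e-08), ependyma (-1.42, 0.00311) and clock (-0.0515, 0.0437) lists. Leaving out a library brought 8 of these lists past the threshold. Oligodendrocyte genes were higher without wild-type replicate 1 (camera adjusted p 0.0310), wild-type replicate 3 (0.00271) or deletion replicate 3 (0.0281), but turned to a median of -0.0718 without wild-type replicate 2 (0.461) and were not called without deletion replicate 1 (0.680) or 2 (0.0886). Higher too were cholesterol synthesis without wild-type replicate 3 (1.11e-04) and astrocyte genes without deletion replicate 2 (0.0251). Ependyma genes were lower without wild-type replicate 3 (camera adjusted p 0.00636) or deletion replicate 3 (0.00122), interferon genes without wild-type replicate 1 (0.00651) or deletion replicate 2 (0.0178), and clock genes without deletion replicate 3 (0.0148). Without wild-type replicate 1, HOX paralogs 9 to 13 were higher (median 0.90, camera adjusted p 0.0135), while without wild-type replicate 3 their median was -0.23 (0.267), and mitochondrial mRNAs were higher without wild-type replicate 1 (0.0310) and lower without wild-type replicate 3 (0.0371).

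The libraries parted by genotype along the first principal component, which held 47.7% of the variance. The second held 20.2% and set wild-type replicate 3 apart. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.960 to 0.974 within wild type, 0.974 to 0.983 within the deletion group and 0.939 to 0.962 between groups.

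The authors' deposited table marks many of the same genes. In the authors' deposited table, UBE3A has a fold change of -2.60 with a false discovery rate of 6.89e-11, DCN -6.44 with 3.48e-31 and ACTA2 -56.6 with 6.24e-30. It holds 1268 genes at a false discovery rate under 0.05, 597 higher and 671 lower, among 17614 with a value. Of the 149 genes called here, 148 are also called in the authors' deposited table in the same direction, 26 higher and 122 lower, where independent lists would share 1.06 and 5.24. The exception is C1QTNF6, chosen after its values were seen, with a log2 fold change of -0.60 here. Both analyses used the same 6 libraries, so the overlap is no independent check. All 1212 of the authors' calls that were tested here had the same sign here.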

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

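The covariate for nerve root and meninges genes, the bias-adjusted deviances, the likelihood ratio test and the list tests in the animals of ID prefix 15 were chosen after the data were seen. UBE3A kept its direction in every alternative, with log2 fold changes from -1.51 to -1.08, and its call was lost with the ID prefix block (-1.39), in prefix 15 alone (-1.44), with the root and meninges covariate (-1.08) and without some single libraries (-1.51 to -1.33). Against 149 genes in all, with 26 genes changed in maternal deletion, higher, and 123 genes changed in maternal deletion, lower, no filter gave 237 (77 higher), a mean log2 CPM of at least 1 gave 79 (8 and 71), DESeq2 1362 (569 and 793), voom with quality weights 438 (94 and 344), the likelihood ratio test 1271 (604 and 667), the prefix block 3 (0 and 3) and prefix 15 alone 0. The neuron minus oligodendrocyte covariate gave 601 (139 and 462), the threshold of 0.1 gave 839 (344 and 495), a test against 1.5-fold gave 4 (0 and 4; DCN, COL1A2, COL3A1 and PTGIS), and the root and meninges covariate gave 205 (176 and 29), sharing 1 gene with the 149. Leaving out each library gave 0 to 759 genes, 0 to 120 higher and 0 to 639 lower: 0 without wild-type replicate 1 and without deletion replicates 2 and 3, 6 without deletion replicate 1, 9 without wild-type replicate 2 and 759 without wild-type replicate 3, which shared 147 of the 149. RLE and total-count scaling gave 9 and 6 higher genes. Against 18 lists, 0 passed with an estimated correlation, 4 by fry and 10 with the root and meninges covariate, of which 4 were among the 18, the ribosomal list with its sign turned. The fits of 4 libraries rest on fewer samples and the root covariate nearly follows genotype; for the other settings the cause was not tested. Signs turned, with no adjusted p under 0.05 unless given, for the MAGEL2 log2 fold change with the neuron covariate (-0.0562) and without deletion replicate 3 (-0.370; leaving out each library, -0.370 to 0.389), the MKRN3 log2 fold change in prefix 15 (-0.0779), and the HERC2 log2 fold change with total counts (-0.0527), upper quartile (-0.0362), prefix 15 (-0.146), and without wild-type replicate 1 or 2 or deletion replicate 1 (leaving out each library, -0.0284 to 0.109). With the root and meninges covariate they turned for 14 genes, among them MKRN3 (-2.62), TUBGCP5 (-0.28), the NIPA1 log2 fold change (-1.65), HERC2 (-0.95), ACTA2 (1.80), ADAMTS8 (0.82), PRX (1.48), MYH11 (1.27), COL6A6 (1.04), PI16 (1.55), MYL9 (1.85), GAS2L3 (0.96) and MRGPRF (0.45), and for the glutamate (-0.30), endothelium and mural (0.53), Schwann cell (0.97), blood (0.13), MHC class II (0.68), glucocorticoid (0.97) and ribosomal protein lists (0.56; camera adjusted p 0.00146); the medians of the immediate early (0.41) and dorsal root ganglion (-0.46) lists turned too, while camera kept their direction. Of the comparisons of named genes with an alternative, 351 kept direction and side of the threshold, 248 lost a call, 5 gained 1 and 23 changed sign. For the 18 lists, 284 kept direction and call, 14 lost the call and 7 changed direction, and over all alternatives the other lists passed in 33 cases, from 9 lists. The first component held 46.1% at a prior count of 0.5, and 848 genes in the authors' deposited table lie under 0.01. Other scalings moved the median of all genes to between -0.04 and 0.01, from 0.05. No paired analysis was possible because the labels pair no single animals across genotypes; the ID prefix, shared by animals of both, was used as the block above. Pseudocount alternatives for normalized values were not run because the files hold counts, nor was a count of unique reads, since the files give 1 read column. Depth of 17181003 to 22492366 reads limits genes near the floor, such as GABRG3 with 10 reads.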

Other observations

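All tests of explanations in this part were chosen after the results they bear on were seen, except the splits of the libraries, which were planned.

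HOX genes, which mark position along the cord, gave mixed values. HOXC9 and HOXC10 stood at 1.81 ± 1.63 and 0.562 ± 0.501 CPM in wild type and at 8.04 ± 0.976 and 3.12 ± 0.694 CPM in the deletion group (SD, n = 3 each; edgeR quasi-likelihood adjusted p 0.175 and 0.0910), while HOXB9 stood at 11.4 ± 4.46 and 5.87 ± 5.12 CPM. Ependyma and cilia genes fell into high and low libraries within both genotypes, with list means of 1.84, 1.94 and -0.12 log2 CPM in wild-type replicates 1 to 3 and 0.06, 0.38 and 1.92 in deletion replicates 1 to 3. The inhibitory neuron enzymes GAD1 and GAD2, chosen after their values were seen, gave log2 fold changes of 0.01 and 0.16, far from the 3.19 of CHAT in motor neurons; the difference between these genes was not tested.

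The extent of the loss at UBE3A was tested on neighbouring genes. If the deletion reached a gene expressed from both alleles, and cell make-up were alike between groups, that gene would lie near a log2 fold change of -1. NDN, MAGEL2 and MKRN3, the nearest tested genes on their side by RefSeq order in Sscrofa11.1, are paternally expressed, so a loss of their maternal copy would leave their RNA unchanged and stays open. Beyond them OTUD7A, chosen after its values were seen, gave 0.51 with a 95% interval of 0.126 to 0.885. GABRA5 on the other side gave 1.12 with an interval of 0.49 to 1.75. Both intervals lay above -1, which would argue against a loss that reaches either gene if cell make-up were alike. Neuron genes were higher in the deletion group, with a general neuron list median of 0.98. Such a shift could mask the loss of a copy in genes that neurons express, so the test cannot exclude it. Of 17 tested neighbours without the paternally expressed genes, none passed the threshold and 16 had intervals above -1. The exception was ALDH1A3, at -3.07 with an interval of -4.54 to -1.59.

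The largest pattern was the fall of matrix, smooth muscle and Schwann cell genes. A candidate explanation is adhering tissue, such as nerve root, vessel wall and meninges, in the wild-type pieces. A shared source in fixed proportions cannot be told apart from other sources for the matrix genes: the 16 tested members of the matrix list differed by a median of 0.98 log2 units between the highest and lowest wild-type library and the 26 tested Schwann cell, endothelium and mural genes by 0.84, with ranges that overlapped widely. For the Schwann cell genes, the range over wild-type libraries and the range over deletion libraries gave a Spearman rho of 0.32 across the 10 genes (Pearson's r 0.68; permutation p for rho 0.366), so varying amounts of nerve root cannot be told apart from an effect of genotype. Fuller removal of meninges from the deletion pieces cannot be told apart from genotype either, since the lowest wild-type mean of the matrix list lay 1.30 log2 units above the highest deletion mean and the labels record no dissection, and a biological effect of the deletion stays open.

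The higher levels of neuron genes, motor neuron genes most, form another pattern. Wild-type replicate 3 alone is argued against as the whole cause, because without it the median of the general neuron list was still 0.70 and the lowest deletion mean lay 0.44 above the highest remaining wild-type mean. A larger share of grey matter was assumed to raise neuron classes alike, which was not tested, and the GABA and glycine list also holds receptor genes. The mean of the motor neuron list lay 1.59 log2 units below that of the GABA and glycine list in wild type. In the deletion group it lay 0.05 below, a difference of 1.54, but single libraries overlapped (exact permutation p = 0.3, smallest possible 0.1). A larger share of grey matter therefore cannot be told apart from an effect of genotype. Pieces from different levels of the cord remain open too, with a difference of 1.03 log2 units in the mean of HOX paralogs 9 to 13 that likewise overlapped between groups (exact permutation p = 0.3). Wild-type replicate 3 carried most of the difference in this mean, at -0.57 against 1.76 and 1.28 in wild-type replicates 1 and 2. Deletion replicates 1 to 3 had 1.64, 1.66 and 2.25. Without wild-type replicate 3 the median log2 fold change of the list was -0.23. Single genes still differed without that library. HOXC9 was at most 3.34 CPM in wild-type replicates 1 and 2 and at least 6.98 CPM in the deletion libraries. HOXC10 was at most 1.11 and at least 2.41 CPM. HOXB9 went the other way, at least 13.5 against at most 11.8 CPM, and HOXA9 overlapped. With all libraries, 3 of the 5 tested genes were positive and 2 negative. A biological effect of the deletion was not tested apart from these.

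The lower immediate early genes could come with the extra tissue or reflect handling. RNA of Schwann cells and smooth muscle was not told apart from genotype by their spread. The 19 tested immediate early genes outside the Schwann cell list, FOS and EGR1 among them, were compared over wild-type libraries. They differed by a median of 0.76 log2 units, with single genes from 0.36 to 1.63. The Schwann cell, endothelium and mural genes differed by a median of 0.84, with single genes from 0.12 to 3.47. Because these ranges overlapped, the test cannot decide, and close medians do not show a shared source. Stress or delay before freezing cannot be told apart from genotype, since heat shock genes had a median of -0.0363 (camera adjusted p 0.629) and the labels give no times. A matrix-rich source remains open as well, and with the root and meninges covariate, which nearly follows genotype, the median of the list was 0.41. An effect of the deletion on these genes stays open.

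With 3 libraries against 3 there are 10 splits, so no share under 0.05 can be reached. The real split gave 149 genes, 26 higher and 123 lower, and the highest other split gave 3, with highest counts of 1 higher and 3 lower; in each case 1 of the 10 splits, the real split, reached the real count. For gene lists, 2 of the 10 splits gave 18 or more, and the highest other split gave 20, the split that exchanges wild-type replicate 3 and deletion replicate 2. Every split passed at least 12 lists, which points to a structure of the samples shared by genes within lists.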
